A study of Mus musculus with 12 samples.

How the data were processed

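Total RNA from 12 cultures of E14 mouse embryonic stem cells was profiled on one-colour Illumina bead arrays: 6 cultures with a short hairpin RNA against luciferase (Luc), 3 with one against Jmjd1a and 3 with one against Jmjd2c. Per the labels, each culture was transfected with 2 µg of hairpin plasmid, RNA was taken with Trizol and column purification, and 500 ng of total RNA was made into biotin-labelled cRNA with the TotalPrep kit. The labels state puromycin at 1 µg/ml for 4 days for the Luc cultures only, so whether the knockdown cultures were selected alike is not given in the sources used here.

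The deposited values are probe intensities on a linear scale, 1 per probe and array for 46133 probes. Between 35.0% and 36.8% of them lie below 0 on each array, which shows that a background was subtracted. The means of the arrays lie close together, as scaled arrays or equal amounts of RNA would give, and the values were taken as already scaled by the authors, which was not tested. How the background was subtracted, and whether and how the arrays were scaled, is not given in the sources used here. The plan fixed beforehand was quantile normalization of linear values, unless their distributions showed that they were already normalized. The close means were taken as showing this, and the values were used as deposited, with no further normalization. The distributions were not equal: the log2 median of probes above 32 on every array ran from 7.91 (Jmjd1a replicate 2) to 8.11 (Jmjd2c replicate 3). Results with quantile normalization are given as an alternative. Intensities under 32 were set to 32, values were put on the log2 scale, where this floor is 5, and the 15853 probes above 32 on at least 3 of the 12 arrays were tested. A fold against a group whose arrays all lie at the floor is a lower bound and is written as at least that fold. The floor also removes the spread of such arrays, so SE and p-values of these probes do not measure it.

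Gene symbols come from the array's own probe annotation: 29542 probes carry 1 symbol (17658 genes), 11 carry several and 16580 carry none. Of the tested probes 12453 carry 1 symbol (9233 genes), 3 several and 3397 none. Gene identifiers of 29484 probes were found in a gene table of assembly GRCm38.p6, used for names only, and 0 symbols needed an update. No coordinates are given.

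Group differences were estimated with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on all 12 arrays with the 3 groups in one fit, which leaves 9 residual degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over the tested probes, and a probe is called at an adjusted p under 0.05. Every adjusted p of a gene is from limma and two-sided. The comparisons were Jmjd1a against Luc, Jmjd2c against Luc, and Jmjd1a against Jmjd2c. Intensities are given as mean ± SD over arrays without the floor, and log2 changes as estimate ± SE. The targeted genes were also tested by an exact two-sided permutation test of the log2 values.

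A set of 24 gene lists with 862 entries was written from general knowledge. On the array 800 entries were matched, and 638 were tested. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe per gene, the one with the highest mean. Camera asks whether a list's genes rank higher or lower than the other genes. It was repeated with a correlation estimated per list, and fry, which asks whether a list's genes move on balance one way, was run beside it. The p-values were adjusted over the 24 lists. The lists cover pluripotency and naive ES cell factors, primitive and visceral endoderm, mesoderm and primitive streak, neuroectoderm and epiblast, trophectoderm and placenta, mesenchymal and fibroblast markers, germline genes and 2-cell-stage genes. Others cover the interferon response, p53 targets, G1/S and DNA replication, G2/M and mitosis, glycolysis and hypoxia, heat shock and chaperones, unfolded protein and amino acid stress, cholesterol biosynthesis, immediate early genes and imprinted genes. The remaining lists hold histone demethylases, H3K9 methylation and heterochromatin, Hox genes, ribosomal proteins, oxidative phosphorylation, and erythroid, blood and macrophage markers.

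The comparisons, the floor, the filter, the test, the lists and the rule for naming genes were fixed before the data were examined. By that rule the text names the targets, the 10 largest rises and the 10 largest falls of each knockdown among called probes with 1 symbol on which all 3 knockdown arrays lie beyond all 6 Luc arrays, with 1 probe per gene and no clone or model names. It also names up to 3 of the largest called rises and falls of each list, the 5 largest differences each way of the direct contrast, and always Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Tcl1 and Tfcp2l1. Zfp57 was also to be named, and as no probe carries that symbol it was not analysed here. Genes may be left out where a list is summarised by a count.

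The array sets were seen in the data, in which probes at background part Luc replicates 1 to 3 and the Jmjd1a arrays from Luc replicates 4 to 6 and the Jmjd2c arrays. The fit with the set as a term, which leaves 8 residual degrees of freedom, was added after that, and its values are called within-set. In it each knockdown is set against the Luc arrays of its own set, and the direct difference is the difference between these effects.

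Alternatives fixed in advance were quantile normalization, median scaling of bright probes, floors of 10 and 100, no filter, a stricter filter at 128, an intensity trend with robust eBayes, array weights, a fit of only the 2 groups compared, a replicate block, stricter thresholds (adjusted p under 0.01, or a fold change of at least 1.5 besides), either set of Luc arrays alone as control, 1 value per gene averaged over probes, and leaving out each array in turn. Overlaps were set against simulated unchanged groups, in 20 simulations of each kind.

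The procedure was tested on simulated data of the same size, 15853 probes with 100 changed by 1.5-fold and 100 by 3-fold per knockdown. For the fit of 3 groups the noise was the spread left by that fit, with no sets, and for the fit with the set as a term the set difference was kept. For Jmjd1a the fit of 3 groups recovered 46.0% and 79.0% of them with 3.85% false calls, and for Jmjd2c 48.0% and 80.0% with 4.48%. The simulation for the fit of 3 groups held no sets, so its rates need not hold for the arrays here, which fall into sets. The fit with the set as a term recovered 67.0% and 89.0% with 3.70% false calls for Jmjd1a, and 69.0% and 96.0% with 11.3% for Jmjd2c. The 11.3% is more than an adjusted p under 0.05 should give, which limits the within-set calls for Jmjd2c. Of 20 simulated lists the 1 that was shifted was found and 0 others were called by camera in either fit. Figures were drawn with matplotlib 3.10.9.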

Results

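The series profiled mRNA in 12 cultures of E14 mouse embryonic stem (ES) cells, a line grown on gelatin with LIF and without feeder cells. Each culture received 2 µg of a plasmid that expresses a short hairpin RNA. In 3 cultures the hairpin targeted Jmjd1a (current symbol Kdm3a), and in 3 it targeted Jmjd2c (Kdm4c). Both genes encode histone demethylases that act on methylated lysine 9 of histone H3. The 6 control cultures received a hairpin against firefly luciferase (Luc), a gene that mouse cells lack. The series text calls the samples of a group biological replicates and sets 3 arrays of each knockdown against all 6 Luc arrays. Each RNA sample was hybridised to a one-colour bead array with 46133 probes. Mean intensity per array was 236 to 245, and between 13591 and 14996 probes per array lay above an intensity of 32. The 15853 probes that did so on at least 3 arrays were tested. The number of arrays limits the precision of every value given here.

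The arrays fell into 2 sets that the labels do not name. As read from the data, one set held Luc replicates 1 to 3 and the Jmjd1a arrays, and the other held Luc replicates 4 to 6 and the Jmjd2c arrays. The within-set values given here rest on this reading. In the order of the series, Luc replicates 1 to 3 alternate with the Jmjd1a arrays and Luc replicates 4 to 6 with the Jmjd2c arrays. Across the tested probes, log2 values of replicates of the same group and set correlated with r = 0.995 to 0.997, while Luc replicates 1 to 3 correlated with Luc replicates 4 to 6 at r = 0.962 to 0.964. Between these Luc sets 9199 probes differed in limma's test, 5889 of them higher and 3310 lower in replicates 4 to 6. Each knockdown has 3 Luc arrays of its own set. The change against those 3 arrays, from a fit with the array set as a term, is given beside the change against all 6 and called the within-set change. As 3 of the 6 Luc arrays belong to the other set, the change against all 6 also holds part of the difference between the Luc sets. Where 2 signed values stand in parentheses after a gene, the first is the log2 change against all 6 Luc arrays and the second the within-set change.

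**Figure D1:**
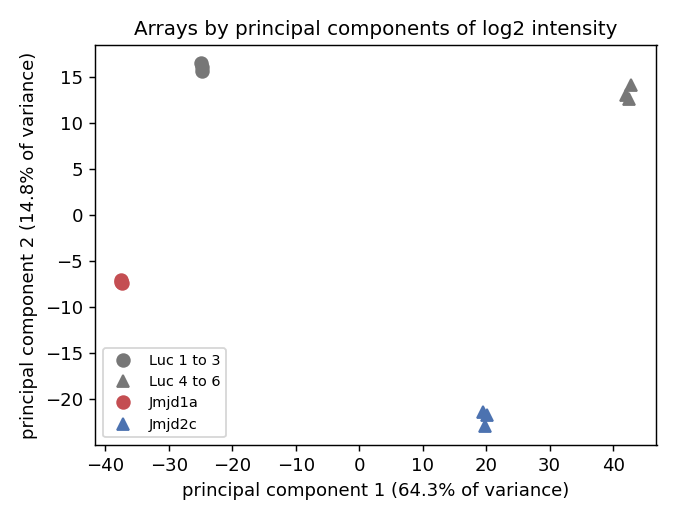
Principal component scores (no unit) of the 12 arrays over the tested probes, with 1 point per array, colours for Luc, Jmjd1a and Jmjd2c, circles for the set of Luc replicates 1 to 3 and triangles for the set of Luc replicates 4 to 6. The first component, 64.3% of the variance, places all circles below 0 and all triangles above 0, and the second, 14.8%, places every knockdown array below the Luc arrays.

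The targeted transcripts were measured first, since they check the labels. In the Jmjd1a arrays both informative Kdm3a probes fell. Probe 101980097 read an intensity of 239 ± 17.6 (SD, n = 3) against 669 ± 90.1 (n = 6) in Luc, a log2 change of -1.48 ± 0.11 (SE) that left 36.0% of the Luc level (limma adjusted p = 8.48e-06). Probe 103780008 read 809.8 ± 35.8 against 1878 ± 311, a change of -1.20 ± 0.12 that left 43.6% (adjusted p = 8.98e-05). Their within-set changes were -1.65 and -1.40. In the Jmjd2c arrays Kdm4c read 104 ± 2.36 (n = 3) against 294 ± 25.9 (n = 6), a change of -1.49 ± 0.08 that left 35.5% (adjusted p = 6.88e-06), with a within-set change of -1.38. Every knockdown array lay below every Luc array on these 3 probes, and the two-sided exact permutation p was 0.0119 for each, the smallest that the 84 splits of 9 arrays can give. Kdm4c differed from Luc by 0.13 in the Jmjd1a arrays (adjusted p = 0.293, within-set 0.02). The Kdm3a probes differed from Luc by -0.00 and -0.10 in the Jmjd2c arrays (adjusted p = 0.990 and 0.665), with within-set changes of 0.17 and 0.11 (adjusted p = 0.0487 and 0.212). A further probe of each gene read at background and was not tested.

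**Figure D2:**
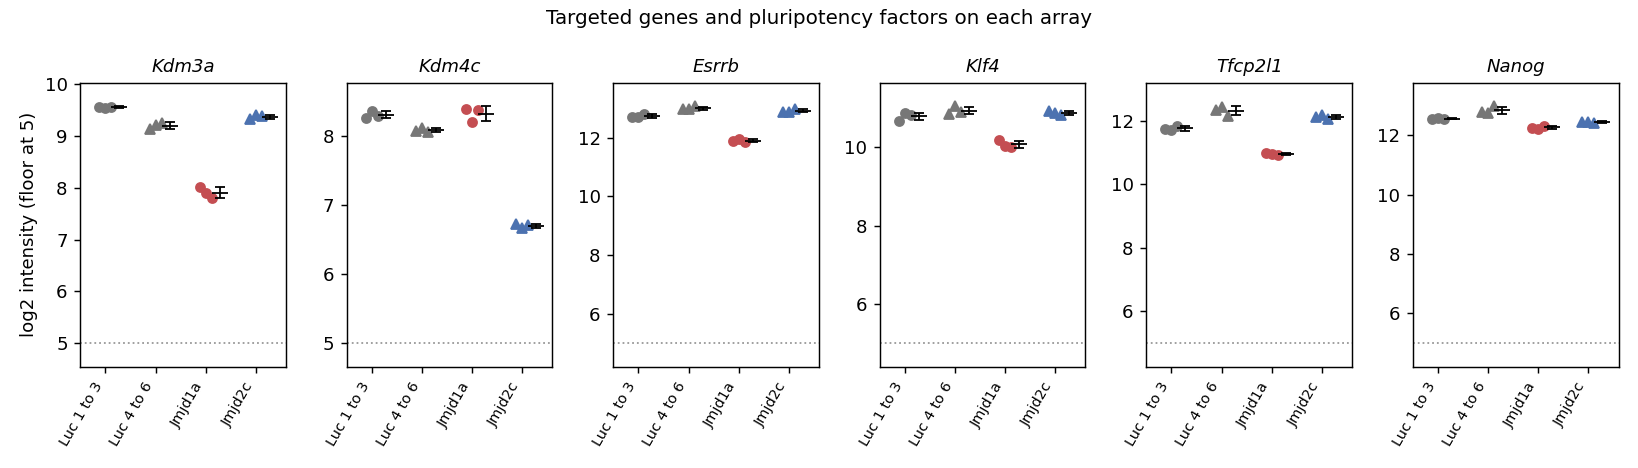
Log2 intensity per array of Kdm3a, Kdm4c, Esrrb, Klf4, Tfcp2l1 and Nanog in the Luc, Jmjd1a and Jmjd2c arrays, with 1 point per array, bars for the mean and SD, a dotted line at the floor of 5, circles for the set of Luc replicates 1 to 3 and triangles for that of replicates 4 to 6. Against Luc, Kdm3a was lower in the Jmjd1a arrays (-1.48), Kdm4c in the Jmjd2c arrays (-1.49), and Esrrb (-0.97), Klf4 (-0.79), Tfcp2l1 (-1.09) and Nanog (-0.43) in the Jmjd1a arrays.

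The first comparison asked which transcripts change when Jmjd1a is depleted in ES cells. Transcripts of several regulators of naive pluripotency fell, among them Esrrb, from an intensity of 7485 ± 819 (SD, n = 6) in Luc to 3812 ± 120 (n = 3), Tfcp2l1, from 4302 ± 949 to 1987 ± 58.1, and Klf4, from 1858 ± 152 to 1076 ± 70.2. The meiosis genes Rec114 and Aurkc and the Akt coactivator Tcl1 fell as well. Transcripts of Fgf5, a marker of the postimplantation epiblast, rose from 18.0 ± 17.5, with 2 of 6 Luc arrays above the floor, to 144 ± 2.68, and those of the chemokine Cxcl12 rose from below the floor on every Luc array to 147 ± 6.46. In all, 1331 probes rose and 1491 fell (911 and 1085 genes), and 166 and 268 of them changed by at least 2-fold.

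The largest rises, as log2 change ± SE, were those of the carbonic anhydrase Car2 (2.97 ± 0.69, within-set 1.64) and the Wnt-responsive transcription factor Sp5 (2.83 ± 0.65, within-set 1.58). They were followed by Fndc3c1 (2.60, 1.90), Mfap3l (2.36, 1.88), the kinase Pim2 (2.34, 1.45), the sodium-iodide transporter Slc5a5 (2.34, 1.75), the POU factor Pou3f1 (2.24, 0.87) and the heparan sulfate sulfotransferase Hs6st2 (2.23, 1.72). Cxcl12 (2.20 ± 0.05, within-set 2.20), at least 4.59-fold higher, and Fgf5 (2.12 ± 0.07, within-set 2.06) completed the first 10. The order is by the change against all 6 Luc arrays, which holds part of the difference between the Luc sets. For Car2, Luc replicates 4 to 6 differed from 1 to 3 by -2.67, and within the set Cxcl12 and Fgf5 rose more than Car2. The largest falls were those of Rec114 (-2.99 ± 0.40, within-set -2.21), Got1l1 (-2.82 ± 0.75, within-set -1.37) and Aurkc (-2.65 ± 0.53, within-set -1.63). Stard8 (-2.40, -1.81), Mmrn2 (-2.33, -1.60), Tcl1 (-2.32, -1.66), the transcriptional regulator Aire (-2.24, -1.61), the ER retention receptor Kdelr3 (-2.18, -1.15), the arginine methyltransferase Prmt8 (-2.14, -1.79) and Fam78a (-2.10, -1.72) came next. Tcl1 and Prmt8 were below the floor on every Jmjd1a array and thus at least 5.00-fold and at least 4.42-fold lower. Adjusted p of these 20 genes lay between 1.55e-09 for Cxcl12 and 0.0485 for Pou3f1. For Cxcl12 every Luc array was set to the floor, so its SE and adjusted p do not measure the spread of the Luc arrays. The same holds in part for Fgf5.

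Of 38 tested genes in the list of pluripotency and naive ES cell factors, 15 fell, 1 rose and 22 did not pass (16 and 2 adjusted over the list alone). The list as a whole was lower (camera adjusted p = 0.0478), with adjusted p = 0.160 with an estimated correlation. Within the set 17 fell and 2 rose, and adjusted p was 2.51e-05, or 0.0230 with an estimated correlation. The genes that fell included Tbx3 (-1.51, -0.93), Tfcp2l1 (-1.09, -0.81), Esrrb (-0.97, -0.83), Klf4 (-0.79, -0.71), Nanog (-0.43, -0.29) and Zfp42 (-0.33, -0.45), and the gene that rose was the Nodal antagonist Lefty1 (0.70, 0.40). Pou5f1, with a change of 0.21 ± 0.14 (adjusted p = 0.316), and Sox2, with -0.18 ± 0.06 (adjusted p = 0.0724), did not pass, and their within-set changes were -0.04 and -0.16. Against Luc replicates 4 to 6 alone, which belong to the other set, the list turned to higher without passing (adjusted p = 0.860). Single arrays ended the call on the list against all 6 Luc arrays: adjusted p was 0.0756, 0.124 and 0.0927 without Luc replicate 1, 2 or 3, and 0.0505, 0.0521 and 0.0517 without Jmjd2c replicate 1, 2 or 3.

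Some immediate early and imprinted genes rose. Of 21 immediate early genes 8 rose and 13 did not pass (9 rose and 2 fell adjusted over the list alone), with Ccn2 (1.69, 1.32) and the HLH inhibitors Id2 (1.54, 0.62) and Id3 (1.39, 0.62) as examples. The list was higher (camera adjusted p = 0.00436), with adjusted p = 0.0860 with an estimated correlation. Within the set 11 rose and 1 fell, with adjusted p of 0.000276, or 0.0291 with an estimated correlation. Of 16 imprinted genes 6 rose and 2 fell (10 and 2 adjusted over the list alone). Dlk1 (1.19, 0.68), the growth factor Igf2 (1.10, 0.60) and Grb10 (0.91, 0.76) rose and the amino acid transporter Slc38a4 fell (-0.51, -0.30). That list too was higher (camera adjusted p = 0.00436), with adjusted p = 0.102 with an estimated correlation. Within the set 9 rose and 2 fell, with adjusted p of 0.00239, or 0.0766 with an estimated correlation.

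Of 16 germline genes 4 fell and 12 did not pass, with the same counts adjusted over the list alone, among them Tex14 (-1.52, -0.86) and the receptor Kit (-1.43, -0.97). The list was lower (camera adjusted p = 0.0264), with adjusted p = 0.633 with an estimated correlation, and it did not pass within the set, where 4 fell and 1 rose (adjusted p = 0.0911). Of 38 G2/M genes 4 fell (2 adjusted over the list alone), including Ube2c (-0.62, -0.33) and Cenpa (-0.51, -0.22), with a camera adjusted p of 0.0290 and adjusted p = 0.669 with an estimated correlation. Within the set 3 fell and 2 rose, and the list did not pass (adjusted p = 0.555). Between the Luc sets 13 of the 16 germline genes and 31 of the 38 G2/M genes were higher in replicates 4 to 6.

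Of 20 markers of primitive and visceral endoderm 4 fell and 16 did not pass (6 fell and 1 rose adjusted over the list alone). They included Pga5 (-1.89, -1.31), at least 3.71-fold lower, Gata6 (-0.98, -1.24) and the basement membrane collagen Col4a1 (-0.96, -1.12). The list did not pass against all 6 Luc arrays (camera adjusted p = 0.0523, and 0.481 with an estimated correlation). Within the set 10 of 20 fell and the list was lower (adjusted p = 6.27e-06, and 0.0230 with an estimated correlation). Of 28 p53 targets 6 rose, Perp (1.30, 0.99) and Dusp4 (1.28, 0.96) among them, and 3 fell (7 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0788, and 0.656 with an estimated correlation). Within the set 15 rose and 3 fell and the list was higher (adjusted p = 3.55e-05, and 0.0204 with an estimated correlation). Against all 6 Luc arrays the endoderm list passed without Luc replicate 4, 5 or 6 (adjusted p = 0.0294, 0.0235 and 0.0284), and so did the p53 list (0.0367, 0.0431 and 0.0358). Against Luc replicates 4 to 6 alone the p53 list turned to lower without passing (adjusted p = 0.854).

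Among markers of other lineages, 2 of 15 trophectoderm genes rose, Cdx2 (1.76, 1.21) and Krt8 (0.80, 0.97), and 1 fell, with the same counts adjusted over the list alone. In the mesoderm list 2 of 15 rose, including Msx1 (1.34, 1.34), at least 2.53-fold higher, and 1 fell (3 and 2 adjusted over the list alone). In the neuroectoderm and epiblast list 4 of 18 rose and 5 fell, including the neural factor Sox21 (-0.83, -0.90), and 5 rose and 5 fell adjusted over the list alone. None of these 3 lists passed (camera adjusted p = 0.435 for each), and the median of the mesoderm list (-0.07) and its mean (0.07) differed in sign.

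In all, limma called 2822 of 15853 probes, 47.2% of them higher, and 2524 of these were also called with the same sign within the set, where 2126 rose and 1914 fell. On 2655 of the called probes all 3 Jmjd1a arrays lay beyond all 6 Luc arrays, as they did on 24.8% of all tested probes, where chance gives 2.38% for arrays without sets. Of the 24 lists 5 passed with the preset correlation and each of the 5 was lost with an estimated one, while fry called 9. Without Jmjd1a replicate 1, 2 or 3 the probe count was 1407, 1399 or 1456. Leaving out 1 array also ended the calls on Car2, Sp5, Pou3f1, Got1l1, Kdelr3, Lefty1, Igf2, Dlk1, Nanog, Zfp42, Id2, Id3, Slc38a4, Tex14, Ube2c and Cenpa, with adjusted p of up to 0.142, for Pou3f1, and 0.0521 for Nanog.

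The second comparison asked the same of Jmjd2c. Several markers of primitive endoderm rose: the transcription factor Gata6 went from an intensity of 250.5 ± 51.6 (SD, n = 6) in Luc to 885 ± 55.7 (n = 3), Sox17 from 23.2 ± 20.1, with 2 of 6 Luc arrays above the floor, to 148 ± 12.2, and Col4a2 from 600.1 ± 87.3 to 1601 ± 63.4. The keratin Krt8 of simple epithelia rose from 187 ± 36.8 to 779 ± 32.8. Transcripts of some glycolytic and cholesterol-synthesis enzymes fell, such as Hk2, from 5228 ± 385 to 3420.3 ± 19.3, and Fdps, from 1662 ± 227 to 1165 ± 19.5. In all 1379 probes rose and 517 fell (1018 and 374 genes), and 70 and 41 of them changed by at least 2-fold.

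**Figure D3:**
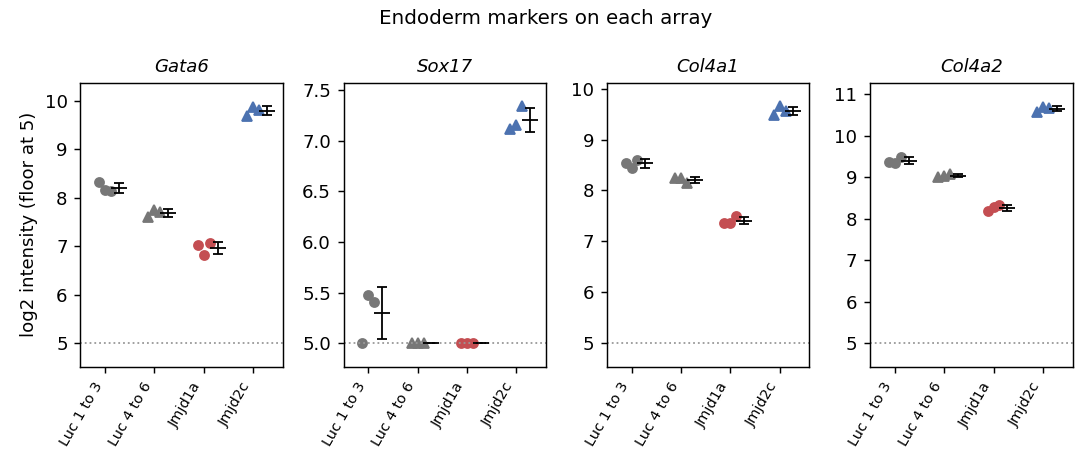
Log2 intensity per array of the endoderm markers Gata6, Sox17, Col4a1 and Col4a2 in the Luc, Jmjd1a and Jmjd2c arrays, with 1 point per array, bars for the mean and SD, a dotted line at the floor of 5, circles for the set of Luc replicates 1 to 3 and triangles for that of replicates 4 to 6. The Jmjd2c arrays lay above all Luc arrays for Gata6 (1.84), Sox17 (2.06) and Col4a2 (1.43), and the Jmjd1a arrays lay below them for Gata6 (-0.98) and Col4a1 (-0.96).

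By the change against all 6 Luc arrays, the largest rises, as log2 change ± SE, were those of Krt8 (2.08 ± 0.14, within-set 1.92) and Sox17 (2.06 ± 0.12, within-set at least 2.21). Next were the forkhead factor Foxq1 (2.02 ± 0.38, within-set 2.74), Gata6 (1.84 ± 0.16, within-set 2.11) and the FGF-binding protein gene Fgfbp1 (1.78 ± 0.47, within-set 2.69). Igf2 (1.68, 2.18), the annexin Anxa3 (1.55, 1.45), the small GTPase Rhob (1.53, 1.21), Zbtb10 (1.51, 1.14) and the heparan sulfate sulfotransferase Hs3st1 followed. Hs3st1 was above the floor on 1 of 6 Luc arrays and 2.82-fold higher on the floored scale, with a within-set change of at least 1.51. For Sox17 and Hs3st1 every Luc array of the Jmjd2c set lay at the floor, so their within-set changes are lower bounds. The largest falls were those of the phospholipase Pla1a (-1.75 ± 0.24, within-set -2.04), at least 3.36-fold lower, the ribosomal protein paralogue Rpl39l (-1.72, -1.19), the growth factor Fgf15 (-1.70, -1.09) and the lysine-degrading enzyme Aass (-1.55, -1.13). Kdm4c itself was next, before Bcas1 (-1.42, -1.79), Kank4 (-1.37, -1.35), Capsl (-1.34, -1.06), the activin subunit gene Inhbb (-1.34, -0.76) and Jakmip1 (-1.25, -1.82). Adjusted p of these 20 genes lay between 4.26e-07 for Hs3st1 and 0.0318 for Fgfbp1. For Hs3st1 the floor removes nearly all spread of the Luc arrays, so its adjusted p does not measure that spread. The same holds in part for Sox17.

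Of 20 endoderm markers 8 rose and 12 did not pass (9 rose adjusted over the list alone). The list was higher (camera adjusted p = 0.000102), with adjusted p = 0.0875 with an estimated correlation. Within the set 13 rose and 3 fell, with adjusted p of 4.94e-05, or 0.0333 with an estimated correlation. Between the Luc sets 12 of the 20 were lower and 5 higher in replicates 4 to 6 (median -0.34, camera adjusted p = 0.00719, and 0.0815 with an estimated correlation), a lower baseline for the within-set change. Of 15 trophectoderm markers 5 rose and 10 did not pass, with the same counts adjusted over the list alone, including Krt8, Krt18 (1.26, 0.80) and the receptor gene Fgfr2 (0.87, 1.19). That list was higher (camera adjusted p = 0.0128), with adjusted p = 0.0875 with an estimated correlation. Within the set 7 rose and 2 fell, with adjusted p of 0.0146, or 0.151 with an estimated correlation. Against Luc replicates 1 to 3 alone, which belong to the other set, adjusted p was 0.0698 for the endoderm and 0.0687 for the trophectoderm list. Of 18 neuroectoderm and epiblast genes Sox21 rose (0.98, 1.05) and 1 fell, the same adjusted over the list alone, and within the set 8 rose and 2 fell.

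The pluripotency list was lower against all 6 Luc arrays (camera adjusted p = 1.06e-05, and 0.00596 with an estimated correlation), with 6 of 38 genes down and 1 up, the same adjusted over the list alone. Within the set 12 fell and 8 rose, and the list did not pass (adjusted p = 0.0735, and 0.186 with an estimated correlation). Eras (-0.80, -0.68), Lefty1 (-0.76, -0.45) and the Nodal coreceptor Tdgf1 (-0.75, -1.05) fell and Nodal rose (0.34, 0.26). The central factors did not pass. Pou5f1 differed from Luc by -0.22 (adjusted p = 0.367, within-set 0.03), Sox2 by -0.17 (0.111, within-set -0.18), Nanog by -0.26 (0.109, within-set -0.40), Zfp42 by -0.21 (0.138, within-set -0.10) and Tcl1 by -0.87 (0.145, within-set -1.54). Klf4 differed by 0.02 (adjusted p = 0.898, within-set -0.05), Esrrb by 0.05 (0.781, within-set -0.09) and Tfcp2l1 by 0.08 (0.791, within-set -0.19), and each of these 3 was negative with median scaling. Within the set Nanog, Sox2 and Tcl1 passed (adjusted p = 0.000395, 0.0312 and 1.34e-06).

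Some genes of cholesterol biosynthesis and glycolysis fell. Of 19 cholesterol biosynthesis genes 6 fell and 13 did not pass (8 fell adjusted over the list alone), and the list was lower (camera adjusted p = 1.37e-06, and 0.00596 with an estimated correlation). Within the set 12 fell, with adjusted p of 0.00215, or 0.0333 with an estimated correlation. Dhcr7 (-0.60, -0.68), Fdps (-0.50, -0.33) and the regulator Srebf2 (-0.44, -0.50) were among them, and 1 of 2 other Srebf2 probes had the opposite sign. After Jmjd1a knockdown 4 of the 19 fell, with the same count adjusted over the list alone, and Dhcr7 was among them (-0.68, -0.61). Of 28 glycolysis and hypoxia genes 5 fell after Jmjd2c knockdown and 23 did not pass, with the same counts adjusted over the list alone. They included Ldha (-0.63, -0.63), Hk2 (-0.61, -0.70) and Pgk1 (-0.51, -0.76). The list was lower (camera adjusted p = 0.000182), with adjusted p = 0.470 with an estimated correlation. Against Luc replicates 1 to 3 alone it turned to higher without passing (adjusted p = 0.665). Within the set 21 of the 28 fell, with adjusted p of 1.03e-11, or 0.00626 with an estimated correlation, and 23 of the 28 had been higher in Luc replicates 4 to 6 than in Luc replicates 1 to 3.

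Of 28 p53 targets 9 rose and 19 did not pass (12 rose adjusted over the list alone), among them Perp (1.05, 1.36) and Plk2 (0.86, 0.66). The list was higher (camera adjusted p = 1.06e-05), with adjusted p = 0.301 with an estimated correlation. Within the set 13 rose and 3 fell, with adjusted p of 0.00623, or 0.0405 with an estimated correlation. Of 21 immediate early genes 3 rose (4 adjusted over the list alone), Ccn2 (0.73, 1.10) among them, and of 16 imprinted genes 3 rose (5 adjusted over the list alone), Grb10 (1.17, 1.32) among them. Neither of these lists passed (camera adjusted p = 0.646 and 0.255). Within the set both were higher (adjusted p = 0.0409 and 0.00464), with adjusted p = 0.136 and 0.0694 with an estimated correlation.

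The lists of G1/S genes, ribosomal proteins and oxidative phosphorylation were lower against all 6 Luc arrays by small amounts. Of 38 G1/S genes Chaf1b (-0.45, -0.45) and Pold1 (-0.24, -0.18) fell, 1 of them adjusted over the list alone (camera adjusted p = 0.000796), with adjusted p = 0.441 with an estimated correlation. Within the set 9 rose and 4 fell, and the list turned to higher without passing (0.669). Of 59 oxidative phosphorylation genes 4 fell, Atp5c1 (-0.35, -0.24) among them, and adjusted over the list alone limma called 0, with 15 falls at unadjusted p under 0.05. That list had a camera adjusted p of 1.27e-07 and a fry adjusted p of 0.00610, with adjusted p = 0.0875 with an estimated correlation and 0.143 within the set. Of 61 ribosomal protein genes limma called 0, over all probes and adjusted over the list alone, with 2 falls at unadjusted p under 0.05. Camera gave an adjusted p of 0.000293 and fry 0.325, with adjusted p = 0.470 with an estimated correlation and 0.545 with quantile normalization. Within the set 18 ribosomal protein genes fell and 4 rose (adjusted p = 0.000791, and 0.321 with an estimated correlation). Of 38 G2/M genes limma called 0 against all 6 Luc arrays, with 2 rises and 3 falls at unadjusted p under 0.05 (camera adjusted p = 0.183, fry 0.936), and 16 fell within the set (adjusted p = 5.25e-05, and 0.00982 with an estimated correlation). Without Luc replicate 1 or 3 the G2/M list passed against the remaining Luc arrays (adjusted p = 0.0492 and 0.0439). Against Luc replicates 1 to 3 alone it turned to higher without passing (adjusted p = 0.119), and 31 of its 38 genes had been higher in Luc replicates 4 to 6 than in 1 to 3.

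Limma called 1896 probes, 72.7% of them higher, and 1867 of these were also called with the same sign within the set, where 3288 rose and 2888 fell. The share of higher calls was 55.5% with quantile normalization and 49.1% with median scaling, against 52.3% and 53.9% for Jmjd1a. On 1823 of the called probes all 3 Jmjd2c arrays lay beyond all 6 Luc arrays, as they did on 18.4% of all tested probes, where chance gives 2.38% for arrays without sets. Of the 24 lists 9 passed, and 2 of them, cholesterol biosynthesis and pluripotency, also passed with an estimated correlation. Without Jmjd2c replicate 1, 2 or 3 the probe count was 1036, 1013 or 1036. Leaving out 1 array also ended the calls on Atp5c1, Tdgf1, Inhbb, Jakmip1, Fgfbp1, Nodal, Lefty1, Fdps, Pgk1, Pold1 and Ccn2, with adjusted p of up to 0.163, for Ccn2.

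Setting the knockdowns against each other asks whether their effects differ. Gata6 was lower in the Jmjd1a arrays (125 ± 10.8, SD, n = 3) than in the Jmjd2c arrays (885 ± 55.7, n = 3), a log2 difference of -2.82 ± 0.18 (SE, limma adjusted p = 4.40e-06), and Col4a2 differed by -2.38 ± 0.13. Fgf5 was higher in the Jmjd1a arrays by at least 2.17 ± 0.08, a lower bound, as the Jmjd2c arrays read at or near the floor. The glycolytic gene Ldha was higher in the Jmjd1a arrays as well (0.84 ± 0.08). Each knockdown lies in its own array set, so the direct difference also holds the difference between the sets. The within-set value here is the difference between the knockdown effects, each against the Luc arrays of its own set, and it was -3.35 for Gata6, -2.75 for Col4a2, 2.06 for Fgf5 and 0.85 for Ldha. For Fgf5 the Jmjd2c effect sets arrays at or near the floor against each other. The value of 2.06 is thus the Jmjd1a change alone and tells nothing of an Fgf5 fall with Jmjd2c.

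Among the largest direct differences, Pim2 (2.54, 0.76), Mfap3l (2.43, 1.47), Car3 (2.38, 1.15), Fgf15 (2.31, 1.10), Mmrn2 (-2.94, -1.49) and Foxq1 (-2.83, -4.28) kept their sign within sets, and Car3 was at least 5.19-fold higher. Car2 (2.55, adjusted p = 0.0388) and the stress-induced Nupr1 (-3.29, adjusted p = 0.0397) turned within sets, to -0.11 (adjusted p = 0.693) and 0.20 (adjusted p = 0.247). Got1l1 (-3.09, adjusted p = 0.0260) shrank to -0.19 (adjusted p = 0.247). Without any 1 of the 6 knockdown arrays Car2, Nupr1 and Got1l1 did not pass, with adjusted p of up to 0.0961, 0.101 and 0.0740. Sox21 (-1.81, -1.94), Tbx3 (-1.69, -0.54) and Lefty1 (1.46, 0.85) passed both ways.

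Of 20 endoderm markers 11 were lower in the Jmjd1a arrays and 9 did not pass, with the same counts adjusted over the list alone. The list was lower (camera adjusted p = 0.000142), with adjusted p = 0.200 with an estimated correlation. Within sets 15 were lower and 1 higher, with adjusted p of 1.48e-10, or 0.00470 with an estimated correlation. Of 28 glycolysis genes 4 were higher and 2 lower, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.473). Its median of -0.27 and mean of -0.40 lay below 0 although the test pointed to higher, and with quantile normalization the test pointed to lower (adjusted p = 0.833). Within sets 20 of the 28 were higher, with adjusted p of 1.99e-11, or 0.00470 with an estimated correlation.

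The other lists that passed in the direct contrast did so with the set difference in it. Of 36 unfolded protein response genes 13 were lower (15 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00676), with adjusted p = 0.631 with an estimated correlation. Of 21 immediate early genes 3 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0355, and 0.0596 without Jmjd2c replicate 2), with adjusted p = 0.200 with an estimated correlation. Within sets neither passed (adjusted p = 0.955 for each). Of 38 G1/S genes 5 were higher and 5 lower (7 and 5 adjusted over the list alone) and the list was higher (camera adjusted p = 0.00676), with adjusted p = 0.631 with an estimated correlation. Of 59 oxidative phosphorylation genes 7 were higher and 2 lower (5 and 1 adjusted over the list alone) and the list was higher (camera adjusted p = 0.000235), with adjusted p = 0.278 with an estimated correlation. Within sets the G1/S list turned to lower (adjusted p = 0.0315), with adjusted p = 0.251 with an estimated correlation. The oxidative phosphorylation list did not pass within sets (adjusted p = 0.891). With quantile normalization the immediate early, G1/S and oxidative phosphorylation lists did not pass directly (adjusted p = 0.0611, 0.0575 and 0.126).

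Directly, 3950 probes differed, 1237 higher and 2713 lower in the Jmjd1a arrays. The groups did not overlap on 3938 of them, and on 60.4% of all tested probes. Chance gives 10% for arrays without sets, and the excess also holds the difference between the sets. As deposited the median probe differed by -0.11 log2, which quantile normalization took to 0. The share of higher calls was 31.3% as deposited, 50.3% with quantile normalization and 57.0% with median scaling. Within sets 3844 probes differed, 1966 higher and 1878 lower, and 1368 of the 3950 were among them with the same sign while 2582 were not called. Without Jmjd1a replicate 1, 2 or 3 the direct count was 1870, 1930 or 2021, and without Jmjd2c replicate 1, 2 or 3 it was 2016, 1873 or 2011.

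The calls of the knockdowns against Luc overlapped. Against all 6 Luc arrays 309 probes rose in both and 201 fell in both, where independent lists of these sizes would share 116 and 48.6. A further 25 rose with Jmjd1a and fell with Jmjd2c, and 63 did the opposite. The log2 changes correlated across probes, which are not independent replicates, with r = 0.127 and a covariance of 0.0161. Unchanged groups drawn around the mean of the same Luc arrays (20 simulations) gave r = 0.0101 and a covariance of 0.000223. When each was drawn around the Luc arrays of its set, r was -0.924 and the covariance -0.0731. The simulated groups were centred on the Luc arrays they were set against, so the noise of the shared control is left out. The simulations therefore cannot tell how much of the overlap and of r = 0.127 that noise gives. With each knockdown against the Luc arrays of its own set, which leaves no shared control, 883 probes rose in both and 780 fell in both, where independent lists would share 419 and 319, with r = 0.332 and a covariance of 0.0371. With the Luc sets exchanged, 550 and 329 were shared, where independent lists would share 1354 and 974, and r was -0.541. There 1636 probes rose with Jmjd1a and fell with Jmjd2c, and 3622 did the opposite.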

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

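The fit with the array set as a term and the tests on background probes, on the state of the Luc cultures, on set membership and on the endoderm markers, and the count of splits that keep the sets, were chosen after the results were seen, while the splits of all arrays, the scaling tests and the test with disjoint Luc arrays were fixed before.

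The effects of the knockdowns, each against the Luc arrays of its own set, differed on 3844 probes in limma's test of the difference. Among the genes named for either knockdown, Gata6 (-3.35), Col4a2 (-2.75), Col4a1 (-2.48) and Sox21 (-1.94) had a more negative log2 effect with Jmjd1a than with Jmjd2c, and Lefty1 (0.85) a more positive one. They stand out because limma called each of the 5 against Luc with both knockdowns, in opposite directions.

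Of the 84 named genes tested for a single distant array among the 6 Luc arrays, 1 gene stood out, Hs3st1. Luc replicate 2 read 5.06 on the log2 scale while the other 5 Luc arrays lay at the floor of 5, so the gap is the whole range and its ratio of 1 exceeds Dixon's 95% critical value for 6 arrays. Chance gives about 1 in 20 such genes, and the array lies just above the floor.

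In other splits of the same arrays, 2 of the 84 ways to choose 3 of the 9 Jmjd1a and Luc arrays gave at least the real 2822 probes, the real one included. The highest other count, 9205, came from setting Luc replicates 4 to 6 apart. For Jmjd2c 3 of 84 gave at least the real 1896, and the highest other count, 7376, came from setting Luc replicates 1 to 3 apart. Both splits follow the array sets and point to a structure of the arrays, within which 4040 and 6176 probes were called. Among the 20 splits that take all 3 arrays from the set of the knockdown, 1 reached the real count for Jmjd1a (highest other 751) and 2 for Jmjd2c (highest other 4500, Luc replicates 4 to 6). With 20 splits no share can fall under 0.05, so these counts decide nothing. Splits that mix the sets put the difference between the sets into the spread. The low share over all 84 splits therefore does not exclude chance either. For the direct contrast 1 of the 10 splits gave 3950 probes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

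The first pattern weighed is the difference between Luc replicates 1 to 3 and 4 to 6, on 9199 probes. One scaling factor per array is argued against, since 9000 probes still differed after quantile normalization and 9147 after median scaling. A technical difference between sets of arrays stays open and untested: in 6 of 6 knockdown arrays the 16545 background probes correlated more with the Luc arrays of the same set, by 0.020 to 0.058 between correlations below 0, but the sets were read from such probes. A different state of the cultures stays open as well, since 9 lists, 4 higher and 5 lower, passed with an estimated correlation, as cultures in different states could show. The labels give no batch or date, and both explanations could hold together.

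The second pattern is that the Jmjd2c effect against Luc replicates 4 to 6 ran opposite to the difference of Luc replicates 4 to 6 from 1 to 3 (r = -0.59 across probes, which are not independent replicates). Shared noise of the Luc arrays is argued against by disjoint Luc arrays, which gave r of -0.53 in the choice nearest 0. Scaling is argued against by r = -0.60 after quantile normalization. That the Jmjd2c arrays belong with Luc replicates 1 to 3 is not excluded, though the order of the series speaks against it. In the order of the series they alternate with Luc replicates 4 to 6, while the Jmjd1a arrays alternate with Luc replicates 1 to 3. Over the tested probes the Jmjd2c arrays correlated at r = 0.980 to 0.983 with Luc replicates 4 to 6 and at 0.974 to 0.976 with 1 to 3. The log2 median of bright probes was 8.09 to 8.11 in the Jmjd2c arrays, 8.07 to 8.08 in Luc replicates 4 to 6 and 7.91 to 7.92 in 1 to 3. These correlations and medians may also move with the knockdown. The background probes that in 3 of 3 correlated more with Luc replicates 4 to 6 are those the sets were read from and decide nothing. Besides that membership, an effect of Jmjd2c depletion on the genes that differ between the Luc cultures stays open. So does a state of the Jmjd2c cultures between those of the Luc sets. The design does not part these.

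The third pattern is the rise of endoderm markers in the Jmjd2c arrays. The difference between the Luc sets stays open as part of its cause. Over all 20 markers the median change was 0.52 against Luc replicates 1 to 3 (95% bootstrap interval 0.21 to 0.74) and 0.73 against 4 to 6 (0.13 to 1.48). The smaller of both changes per gene had a median of 0.09 (-0.15 to 0.68). Taking the smaller lowers the median by construction, so that value decides nothing. The intervals resample genes, not cultures. The 8 called markers lay above all 6 Luc arrays and were also called higher within the set. An interferon response to hairpins in general could not be seen, since the Luc cultures also received one. For a response particular to the Jmjd2c hairpin, limma called 0 rises and 1 fall in the interferon list (1 and 1 at unadjusted p under 0.05, fry adjusted p = 0.362). Within the set it called 2 rises and 5 falls. The list gave no sign of such a response, but several members, such as Ifit2 and Gbp2, read near the floor, so it stays open. Fewer ES cells, which would raise markers of other cell types alike, cannot be told apart from a gain of endoderm-like transcripts: the endoderm median of 0.73 exceeded the mesenchymal median of -0.12 by 0.86 within the set, with a 95% bootstrap interval of -0.40 to 1.58, and the mesoderm (0.17, difference 0.57, -0.05 to 1.33), neuroectoderm (0.27, 0.46, -0.34 to 1.28) and trophectoderm medians (0.23, 0.50, -0.25 to 1.26) were above 0, as fewer ES cells would give. The pluripotency list, which fewer ES cells would lower, was lower within the set without passing (camera adjusted p = 0.0735). Its genes moved both ways, so it does not part these explanations either. Off-target silencing by the hairpin sequence was not tested and stays open, and an effect of Jmjd2c depletion on endoderm genes is the biological candidate that the design names.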

How the results depend on the processing

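The fits with the array set as a term, alone or with quantile normalization, and the direct probe counts with 1 Luc set alone were chosen after the data were seen, and the other alternatives were fixed before. Unless a cause is named, the cause was not tested.

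The fall of the targets kept its direction and passed in 42 of 42 values under other settings and in 36 of 36 without single arrays. Of 1504 values of named genes under other settings 1367 kept direction and call, 85 no longer passed, 30 newly passed and 22 reversed. Of the 85, 28 came with a floor of 100, which hides dim genes, 27 with no filter, which tests more probes, and 12 with only the groups compared in the fit. Of 253 list values 151 were the same, 61 no longer passed, 20 newly passed and 21 reversed. Of 48 probe counts 25 stayed within 1.5 times the count reported, and of 33 list counts 18.

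Of the probe counts, Jmjd1a (2822), Jmjd2c (1896) and the direct contrast (3950), the following moved further. A floor of 100 gave 1670 for Jmjd1a and 2359 directly. No filter gave 1441, 1110 and 1604. An adjusted p under 0.01 gave 1179, 818 and 1229, and an adjusted p under 0.05 with a change of at least 1.5-fold gave 1245, 633 and 2055. Both are stricter by construction. Array weights, whose fit gave a convergence warning, gave 4684 and, directly, 9142. A direct fit of only the groups compared gave 8309. Luc replicates 1 to 3 alone gave 8079 for Jmjd2c and 8542 directly. Luc replicates 4 to 6 alone gave 10007, 6042 and 8631. Leaving out a Luc set removes the difference between the Luc sets from the spread. Against Luc arrays of the other set (10007 and 8079) the change itself also holds the difference between the sets, as the direct contrast does. The change against all 6 Luc arrays holds part of it. Against Luc replicates 1 to 3, of its own set, 2076 probes rose and 1782 fell for Jmjd1a. The set as a term gave 6176 for Jmjd2c, and 6061 with quantile normalization.

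A replicate block on numbers 1 to 3 gave 7839 for Jmjd2c and 8391 directly, and 11 lists directly. Numbers gave no sign of pairing: residuals of arrays with the same number correlated at r = -0.01 to 0.11. For Jmjd2c, Luc arrays with the same number lie in the other set. In the order of the series Jmjd2c replicates 1, 2 and 3 stand beside Luc replicates 4, 5 and 6. Residuals of these pairs correlated at r = 0.034, 0.009 and 0.039, and no block was fitted on them. Pou5f1 with Jmjd1a turned to -0.044 with the block, and for lists the glycolysis list turned with Jmjd2c (adjusted p = 0.712) and directly (0.429), and the G2/M list with Jmjd2c (0.136). The block leaves out Luc replicates 4 to 6, so its values resemble those with Luc replicates 1 to 3 alone.

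Named genes that reversed did so as follows, none of them past the threshold after reversal. With the set as a term Car2 turned to -0.11 and Nupr1 to 0.20 directly, and to -0.20 and 0.27 with quantile normalization added. Pou5f1 with Jmjd1a was -0.044 with Luc replicates 1 to 3 alone and with the set as a term, and -0.047 with quantile normalization added. Pou5f1 with Jmjd2c was 0.027 with Luc replicates 4 to 6 alone and with the set as a term. With Jmjd2c Klf4, Esrrb and Tfcp2l1 were -0.083, -0.054 and -0.022 with median scaling, -0.052, -0.087 and -0.19 with Luc replicates 4 to 6 alone and with the set as a term, and -0.087, -0.069 and -0.17 with quantile normalization added. The set term takes the difference between the sets out of the value.

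Of 24 lists 5 passed for Jmjd1a, 9 for Jmjd2c and 5 directly. Camera with an estimated correlation called 0, 2 and 0, and fry called 9 for Jmjd1a and 13 directly. Median scaling gave 8 for Jmjd1a and quantile normalization 2 directly. Luc replicates 4 to 6 alone gave 11 for Jmjd1a, and either Luc set alone 11 directly. The set as a term gave 9 directly, 8 with quantile normalization, and with an estimated correlation 5 for Jmjd2c and 3 directly.

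Lists that reversed, with the adjusted p after reversal, were these. With Luc replicates 4 to 6 alone pluripotency (0.860) and p53 targets (0.854) turned with Jmjd1a, G1/S with Jmjd2c (0.627) and glycolysis directly (0.216). With Luc replicates 1 to 3 alone glycolysis (0.665) and G2/M (0.119) turned with Jmjd2c and glycolysis directly (0.352). With the set as a term G1/S turned with Jmjd2c (0.669, and 0.768 with an estimated correlation) and directly (0.0315, and 0.251), and oxidative phosphorylation directly (0.891, and 0.895). With quantile normalization added, G1/S (0.0577), oxidative phosphorylation (0.865), the unfolded protein response (0.994) and immediate early genes (0.916) turned directly. With quantile normalization alone glycolysis turned directly (0.833).

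For the overlap, 309 probes rose and 201 fell in both, with r = 0.127. At an adjusted p under 0.01 these counts were 120 and 98, with the set as a term 910 and 835, and with each knockdown against the Luc arrays of its set 883 and 780. With the Luc sets exchanged they were 550 and 329, where independent lists would share 1354 and 974. The r was 0.332 with the set as a term and with own-set Luc arrays, and -0.541 with exchanged sets, where each change holds the set difference with opposite sign.

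Without single arrays, probe counts ranged from 1399 to 3625 for Jmjd1a, from 1013 to 2053 for Jmjd2c and from 1870 to 4363 directly. Over 1.5 times fewer came without Jmjd1a replicate 1, 2 or 3 (1407, 1399 and 1456), without Jmjd2c replicate 1, 2 or 3 (1036, 1013 and 1036), and directly without any of these 6 arrays (1870, 1930 and 2021, and 2016, 1873 and 2011), as such a fit has fewer arrays in the group. List counts ranged from 4 to 7 for Jmjd1a, 9 to 10 for Jmjd2c and 4 to 7 directly. Kdm3a ranged from -1.53 to -1.42 and from -1.24 to -1.14, and Kdm4c from -1.52 to -1.46.

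Of 1296 values of named genes without single arrays 1160 were the same, 134 no longer passed and 2 reversed. Klf4 with Jmjd2c, not called, turned to -0.015 without Luc replicate 1 and -0.0053 without Jmjd2c replicate 1, in a range of -0.015 to 0.057. Calls on Id2, Id3, Cenpa, Ube2c and Pou3f1 with Jmjd1a and Pgk1, Ccn2 and Pold1 with Jmjd2c were lost without any of several arrays of both sorts. Without any single array of the own knockdown calls were lost on Car2, Lefty1, Kdelr3, Igf2, Got1l1 and Zfp42 with Jmjd1a, on Atp5c1, Tdgf1, Inhbb, Jakmip1 and Fgfbp1 with Jmjd2c, and on Got1l1, Car2 and Nupr1 directly. Some of these arrays ended the call on Dlk1, Nanog, Tex14, Sp5 and Slc38a4 with Jmjd1a and Nodal, Lefty1 and Fdps with Jmjd2c. The highest adjusted p was 0.163, of Ccn2 with Jmjd2c. Of 276 list values without single arrays 261 were the same, 7 no longer passed and 8 newly passed. The pluripotency list with Jmjd1a was lost without Luc replicate 1, 2 or 3 (0.0756, 0.124 and 0.0927) or Jmjd2c replicate 1, 2 or 3 (0.0505, 0.0521 and 0.0517), and the immediate early list directly without Jmjd2c replicate 2 (0.0596). With Jmjd1a the endoderm and p53 lists passed without Luc replicate 4, 5 or 6, and with Jmjd2c the G2/M list passed without Luc replicate 1 or 3.

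With a floor of 100 Hs3st1 (Jmjd2c) and Msx1 (Jmjd1a) gave no value, since every array lay at the floor. Signal over background limits dim genes in this way.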

Other observations

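The values within sets and the genes named for the Luc sets were chosen after the data were seen.

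Between the Luc sets, camera called 4 lists higher in replicates 4 to 6 and 5 lower with an estimated correlation. Higher were glycolysis and hypoxia (23 of 28 genes higher, 1 lower), G2/M (31 and 2 of 38), the unfolded protein response (25 and 3 of 36), each with adjusted p = 0.0168 with an estimated correlation, and p53 targets (18 and 3 of 28, 0.0359). Lower were oxidative phosphorylation (3 higher and 23 lower of 59), the H3K9 list (2 and 11 of 18), neuroectoderm and epiblast (2 and 9 of 18), each with 0.0168, G1/S (3 and 23 of 38, 0.0258) and 2-cell-stage genes (1 and 6 of 9, 0.0265). Germline genes were higher with the preset correlation (13 and 1 of 16, adjusted p = 0.000504), with adjusted p = 0.0815 with an estimated correlation. Lower with the preset correlation only were the endoderm (5 and 12 of 20, adjusted p = 0.00719, and 0.0815 estimated), pluripotency (11 and 16 of 38, adjusted p = 0.0147, and 0.0891 estimated), immediate early (5 and 10 of 21, 0.0403, 0.111) and imprinted lists (4 and 8 of 16, 0.0147, 0.0904). The stress-induced genes Ddit3, Nupr1 and Bhlhe40, chosen after their values were seen, had the largest rises, with log2 differences of 3.51, 3.49 and 3.26. Their intensities went from 43.0 ± 14.0 to 497 ± 30.8, from 175 ± 9.97 to 1976 ± 79.0 and from 158 ± 19.9 to 1503 ± 68.8 (SD, n = 3 and 3).

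The other lists of the Jmjd1a comparison did not pass. Of 21 mesenchymal genes 8 rose and 5 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.116), of 9 2-cell-stage genes 1 and 1 (3 and 1, 0.0523) and of 16 interferon genes 1 and 1 (the same, 0.768). Of 28 glycolysis genes 3 fell (the same, 0.0523), of 36 unfolded protein response genes 5 (1, 0.0525), and of 16 heat shock genes 1 rose and 2 fell (2 and 2, 0.319). Of 17 histone demethylases 3 rose and 3 fell (the same, 0.963), of 18 genes of H3K9 methylation 1 and 1 (the same, 0.125), of 59 oxidative phosphorylation genes 3 and 9 (the same, 0.866), of 61 ribosomal protein genes 4 rose (the same, 0.435) and of 5 blood genes 3 fell (the same, 0.120). Of 19 cholesterol biosynthesis genes 4 fell (camera adjusted p = 0.153). Of 8 Hox genes limma called 0, with 0 rises and 2 falls at unadjusted p under 0.05 (camera adjusted p = 0.153, fry 0.00518). Of 38 G1/S genes 1 rose and 4 fell (1 and 3, 0.620), and within the set 1 rose and 8 fell and the list was lower (adjusted p = 0.0107), with adjusted p = 0.183 with an estimated correlation.

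In the Jmjd2c comparison 3 of 15 mesoderm genes rose (5 adjusted over the list alone, camera adjusted p = 0.254), 9 of 21 mesenchymal genes rose and 4 fell (the same, 0.268), 1 of 16 germline genes rose (the same, 0.417) and 1 of 16 interferon genes fell (0 adjusted over the list alone, 0.183). Of 16 heat shock genes 4 rose (the same, 0.147), of 36 unfolded protein response genes 5 (the same, 0.183) and of 18 genes of H3K9 methylation 1 (the same, 0.417). Limma called 0 of 9 2-cell-stage genes (unadjusted 1 rise, camera adjusted p = 0.817, fry 0.712), 0 of 17 histone demethylases (unadjusted 3 rises, 0.417, fry 0.00177), 0 of 8 Hox genes (unadjusted 0, 0.533, fry 0.936) and 0 of 5 blood genes (unadjusted 1 rise, 0.668, fry 0.425). Within the set the germline list was lower (1 rose and 10 fell, adjusted p = 4.94e-05, and 0.0637 with an estimated correlation). Within the set the neuroectoderm (8 and 2, 0.00862, 0.0637), heat shock (8 and 0, 0.00854, 0.132) and 2-cell-stage lists (4 and 0, 0.0242, 0.0832) were higher.

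In the direct contrast within sets the G2/M list was higher with Jmjd1a (10 genes higher, 0 lower, adjusted p = 0.00268, and 0.0272 with an estimated correlation). Lists that passed there only with the preset correlation were ribosomal proteins (higher, 0.00186, and 0.379 estimated) and germline genes (higher, 0.0223, 0.251), and, lower, heat shock (0.00611, 0.191), neuroectoderm (0.0122, 0.103), pluripotency (0.0339, 0.209) and G1/S genes (0.0315, 0.251). Median, mean and test of a list differed in sign against all 6 Luc arrays for the mesoderm and interferon lists and histone demethylases with Jmjd1a, and for the germline, neuroectoderm, 2-cell-stage, H3K9 and Hox lists with Jmjd2c, none of which passed. They also differed in sign for the mesenchymal, interferon, glycolysis, imprinted and ribosomal protein lists in the direct contrast, where none of these passed.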
